A study of Homo sapiens with 4 samples.

How the data were processed

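RNA-seq of the embryonal carcinoma line NCC-IT-A3 was analysed in 4 libraries, 2 from cells treated with 100 nM barasertib for 4 days and 2 from cells given DMSO. Per the labels' protocols, cells grew in RPMI medium with 10% serum, RNA was purified on columns, and libraries were made with a stranded kit for polyadenylated RNA. Reads were aligned with HISAT2 to hg19 and summarised per gene with StringTie, per the submitters' processing notes, which give no versions or options. Whether strand was used in the summary is not given in the sources used here.

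Each deposited file holds 3 measures per gene row. Per the file headers, these are coverage, which is the mean depth over the gene and was used as signal to estimate depth, FPKM (fragments scaled by transcript length and library size) and TPM (transcript abundance scaled to a fixed library total). The deposited TPM values sum to 1000000 in every library. The files hold 28165 to 28297 rows and 27685 gene IDs each, since 336 to 407 IDs per library stand on several rows, and these were summed per ID. Symbols were taken from RefSeq (assembly GRCh38.p14, used for names only), which matched 27559 IDs and left 126 unmatched. Positions are those of the files in hg19.

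The files hold no counts, and read number and read length are not given in the sources used here. StringTie computes FPKM from coverage and the number of aligned bases, so the ratio of the deposited coverage to the deposited FPKM gives that number, and its maximum over genes was 4.59 and 4.52 Gb for barasertib and 4.22 and 4.43 Gb for DMSO. This rests on that definition and not on a stated total. The SD of the log2 difference between replicates was 0.25 in both groups, and 0.16 (barasertib) and 0.13 (DMSO) over the 1717 genes with a mean of at least 100 TPM.

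Genes with a mean of at least 1 TPM over the 4 libraries were tested, which left 13938. The test was limma (version 3.58.1 in R 4.3.3) on log2(TPM + 1), with group as the only term, empirical Bayes moderation with a mean-variance trend (2 residual and 4.09 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are differences of mean log2(TPM + 1).

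Before the data were examined, 36 gene lists were fixed, and each with at least 5 tested members (32 lists) was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera asks whether a list moved relative to the other tested genes. With an estimated correlation, camera uses the 2 residual degrees of freedom of this design. The self-contained test fry, from limma as well, used statmod 1.5.0. The same camera test was run for 23 chromosomes. A further 8 lists, used only in the closing section, were written after gene results had been seen.

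The genes named in the text follow a rule set at the same stage: the 15 largest rises and 15 largest falls among called genes whose groups do not overlap; 9 genes fixed by name, among them AURKB, INCENP, BIRC5, CDCA8, POU5F1, SOX2, NANOG and CDKN1A; per list, up to 4 called members with the largest change, or the member with the smallest p; and the 10 most abundant called genes. The rule gave 167 genes. Some genes that the rule names, and 1 gene list, are not reported here. Genes outside it are said to have been named after their values were seen, and the same holds for CD68 and for the parent, sister, host and copy genes set beside loci that share reads.

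The alternatives set at that stage were: no filter on low values, a mean of at least 5 TPM, pseudocounts of 0.1 and 5, FPKM in place of TPM, median-of-ratios scaling, quantile normalisation, no mean-variance trend, robust moderation, the replicate number as a block, each library left out in turn, a 2-fold threshold, an estimated correlation in camera, and fry. A removal of trends with expression level, GC content and transcript length was added after the data were seen, with GC content and length of the longest GENCODE transcript per gene ID. Other splits of the samples were not counted, since groups of 2 are below the size at which that is informative.

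The fit was tested on simulated data: in 5 runs of 13938 genes with the levels and replicate spread of these libraries and 200 changed genes, 73.2% of 1.5-fold and 94.6% of 2-fold changes were called, 4.88% of the calls were unchanged genes, and 1.25% of unshifted lists were called. The simulated genes varied independently of each other, so the share of unshifted lists called does not cover lists whose members vary together. In the real comparison 29.47% of the tested genes were called, a larger share than was changed in the simulation. Python 3.11.15 and matplotlib 3.10.9 were used for the tables and plots. Genes on the Y chromosome were left out of the chromosome test.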

Results

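RNA was measured in NCC-IT-A3, an embryonal carcinoma line, that is, a malignant germ cell line with features of the early embryo. The cells had been kept for 4 days with 100 nM barasertib, an inhibitor of the kinase Aurora B, or with the solvent DMSO as control, and each group held 2 libraries. Aurora B belongs to the chromosomal passenger complex, which corrects the attachment of chromosomes to the spindle and is needed to complete cell division. The values are TPM, a measure of transcript abundance relative to the whole library, for 27685 gene IDs per library. The ratio of coverage to FPKM, which gives the aligned bases behind the values, reached 4.59 and 4.52 Gb in the barasertib libraries and 4.22 and 4.43 Gb in the DMSO libraries. Across the tested genes, the log2 values of replicate libraries correlated with r = 0.992 in both groups, against 0.979 to 0.981 between groups. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are mean TPM ± SD with n = 2 libraries per group, and fold changes are on the log2(TPM + 1) scale, which understates the change of low genes.

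The one comparison of the design asks which transcripts differed between barasertib and DMSO. THY1, a cell surface glycoprotein used as a marker of fibroblasts and stem cells, showed the largest rise, from 7.49 ± 0.480 TPM with DMSO to 116 ± 6.75 TPM with barasertib, a 13.7-fold change. TMEM200B rose from 2.06 ± 0.397 to 33.0 ± 2.12 TPM. The neuropeptide gene GAL rose from 43.8 ± 2.08 to 203.5 ± 15.1 TPM, and the matrix glycoprotein gene THBS2 rose from 6.33 ± 0.293 to 31.6 ± 0.177 TPM. The chemokine receptors CXCR4 and CCR7 rose from 4.38 ± 0.641 to 22.3 ± 1.85 TPM and from 0.676 ± 0.121 to 6.31 ± 1.37 TPM. At the other end, LAMP3, a lysosomal membrane glycoprotein, fell from 37.5 ± 0.589 to 4.01 ± 0.596 TPM. PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, fell from 2378 ± 46.4 to 534.5 ± 12.1 TPM. In the hg19 coordinates of the files, THY1 (gene ID 7070) spans chromosome 11 from 119288651 to 119295695. LAMP3 (gene ID 27074) spans chromosome 3 from 182840003 to 182880667, and PDIA4 (gene ID 9601) spans chromosome 7 from 148700154 to 148725782.

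In all, 3071 of the 13938 tested genes rose and 1037 fell with barasertib (limma, Benjamini-Hochberg adjusted p under 0.05), or 292 and 87 when a change of at least 2-fold was also asked for. Of the called genes, 74.8% were higher in TPM. This share was 44.7% after median-of-ratios scaling (1529 higher, 1891 lower) and 50.9% after quantile normalisation (1649 higher, 1590 lower). Median-of-ratios scaling and quantile normalisation move the median log2 change of all tested genes, 0.11 in TPM, by -0.12 and -0.12. The medians of gene lists are therefore given below as their difference from the median of all tested genes, and the members that pass the test in the same direction under all 3 scalings are counted. Over all genes these were 1395 higher and 982 lower. In TPM without barasertib replicate 1 there were 1365 higher and 601 lower genes, and without barasertib replicate 2 there were 1598 and 662. Without the mean-variance trend 674 genes were lower. Counts of list members without each library in turn are given in the order barasertib replicate 1, barasertib replicate 2, DMSO replicate 1 and DMSO replicate 2.

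**Figure D1:**
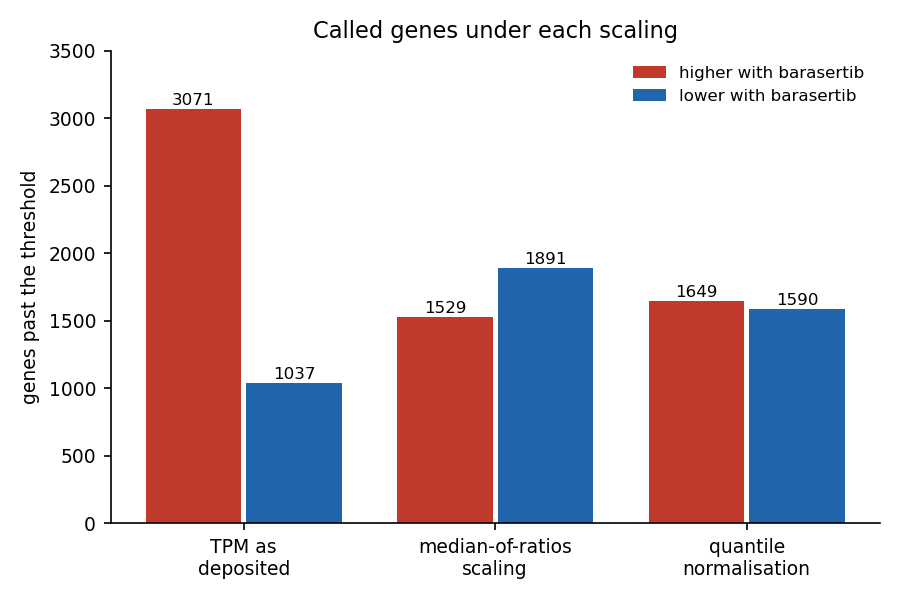
Bars give the number of genes past the adjusted p threshold that were higher (red) or lower (blue) with barasertib, for TPM as deposited and for both other scalings of the same 4 libraries. The higher genes number 3071, 1529 and 1649, and the lower genes 1037, 1891 and 1590.

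**Figure D2:**
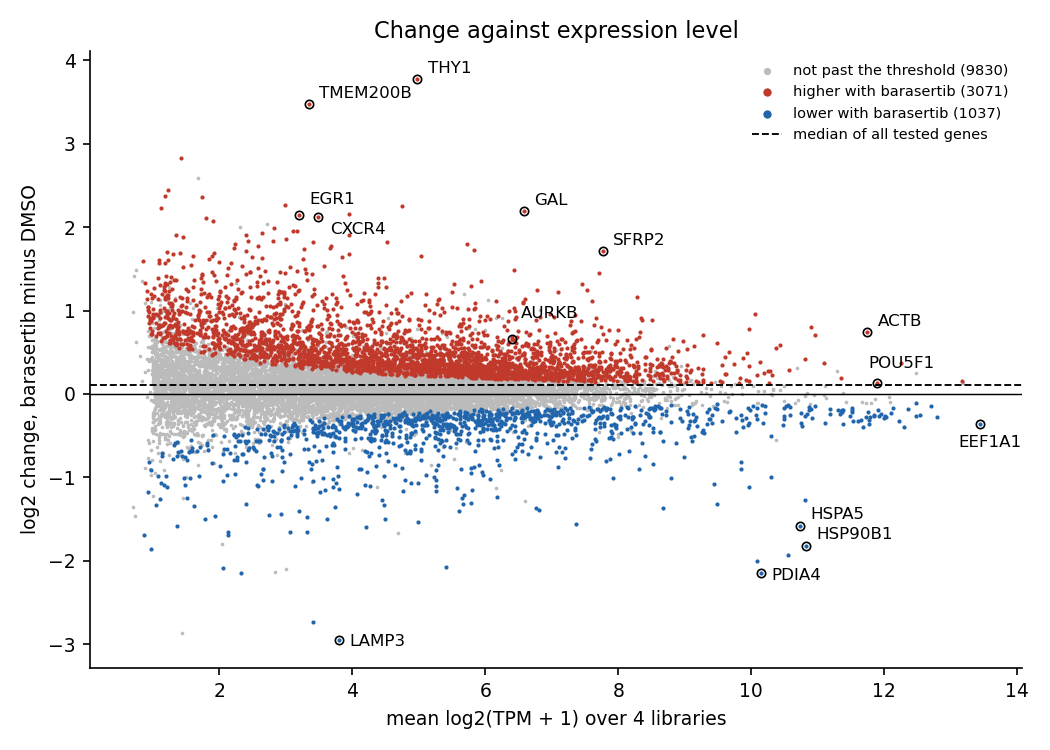
Each point is 1 of the 13938 tested genes, with its mean log2(TPM + 1) over the 4 libraries on the x axis and its log2 change on the y axis. The dashed line marks the median of all tested genes (0.11), and circles mark genes with their symbols, from THY1 at 3.78 to LAMP3 at -2.95.

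Genes of protein folding and stress in the endoplasmic reticulum (ER) fell. HSPA5, the main ER chaperone of the Hsp70 family, fell from 2936 ± 93.1 to 983 ± 53.4 TPM, and HSP90B1, its Hsp90 counterpart, fell from 3407 ± 24.4 to 966 ± 32.5 TPM. The transcription factor gene ATF5 fell from 52.7 ± 0.0788 to 17.6 ± 1.34 TPM. Of the 23 tested members of the unfolded protein and integrated stress response list, 19 fell and 2 rose, with the same counts when adjusted over the list alone. The 19 also fell under all 3 scalings. The members that rose were ATF3 and PPP1R15A, named here after their values were seen, at log2 changes of 0.32 and 0.31, and neither passed the test under all 3 scalings. With any 1 of the 4 libraries left out, 1 member rose and 16 to 18 fell. The list median lay at -0.62 relative to all tested genes. The stress response list had a camera adjusted p = 2.13e-18, and adjusted p = 0.191 with an estimated correlation. Summed over the list, expression was 14975 ± 119 TPM with DMSO and 7009 ± 129 TPM with barasertib. Outside the list, the stress-induced gene NUPR1 fell from 86.9 ± 8.14 to 19.8 ± 0.628 TPM and DERL3, a component of ER-associated degradation, from 9.60 ± 0.443 to 1.43 ± 0.588 TPM.

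Messages of the drug target and of mitosis rose. AURKB, which encodes Aurora B, rose from 66.5 ± 2.22 to 105.5 ± 0.708 TPM, and INCENP, a partner in its complex, rose from 43.1 ± 1.19 to 68.8 ± 3.56 TPM. The partners BIRC5 (survivin) and CDCA8 (borealin) rose from 23.8 ± 0.917 to 41.7 ± 0.0780 TPM and from 66.1 ± 2.0 to 92.2 ± 2.36 TPM. Of 23 tested members of the chromosomal passenger complex and spindle checkpoint list, 19 rose and none fell (20 and 0 when adjusted over the list alone). Under all 3 scalings 17 rose, and the list median was 0.42 relative to all genes. The passenger complex and checkpoint list had a camera adjusted p = 7.28e-08, and adjusted p = 0.191 with an estimated correlation. In the G2 and mitosis list, 30 of 32 rose (31 when adjusted over the list alone), 28 under all 3 scalings, at a median of 0.46. The mitosis list had a camera adjusted p = 4.35e-13, and adjusted p = 0.191 with an estimated correlation. There, the mitotic kinase gene CDK1 rose from 58.8 ± 0.437 to 108 ± 4.62 TPM and the kinesin gene KIF20A from 48.3 ± 0.898 to 90.6 ± 0.834 TPM. Members of these lists changed by less than 2-fold.

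**Figure D3:**
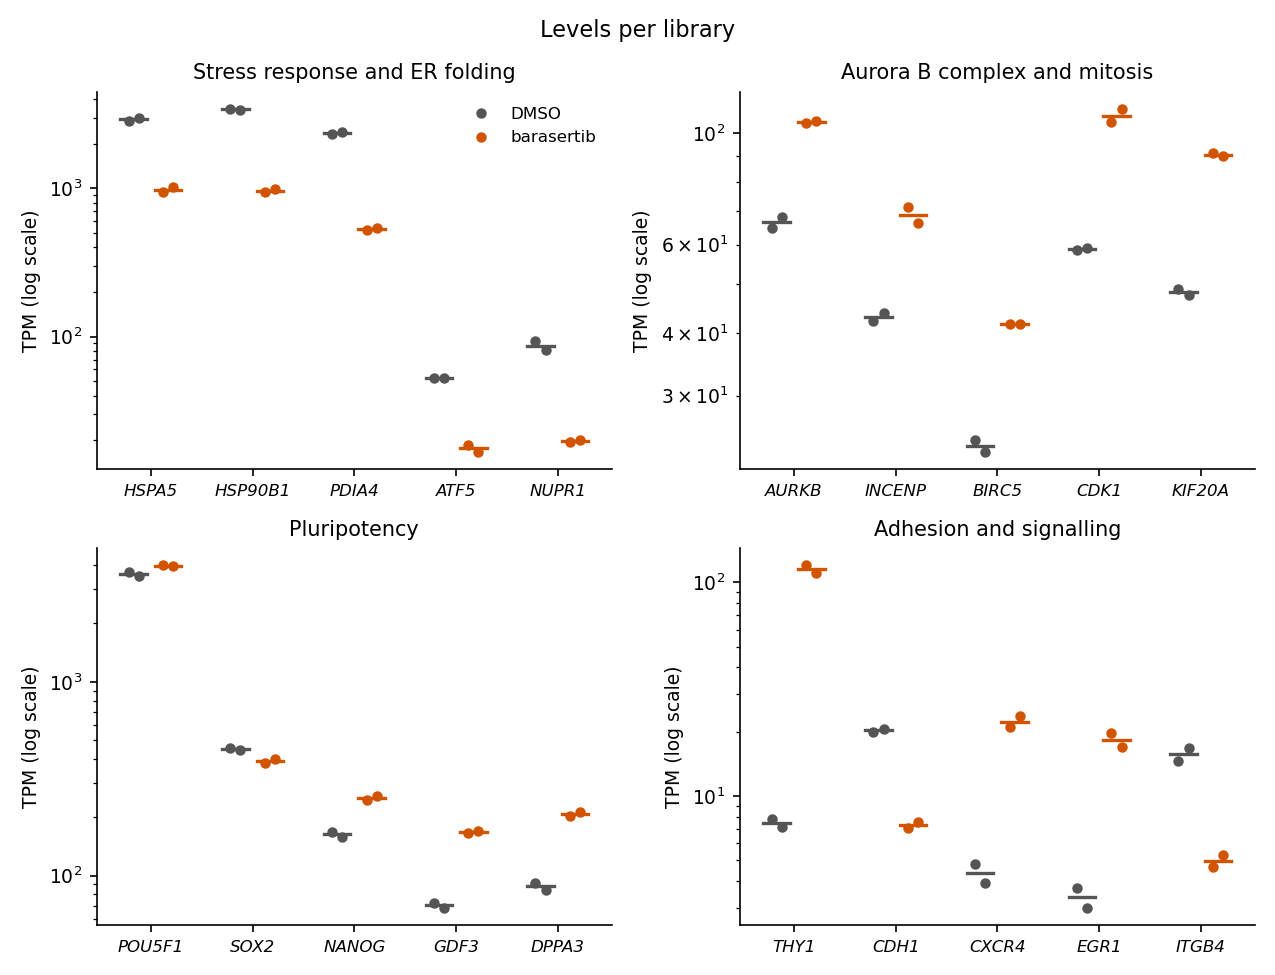
TPM of 20 genes in each library, on log axes, for DMSO (grey) and barasertib (orange), with 1 point per library and a line at the group mean of n = 2. Groups lie apart for each gene shown, HSPA5 falling from 2936 to 983 TPM and AURKB rising from 66.5 to 105.5 TPM. All genes shown were called, and no called gene had overlapping groups, so this separation adds no evidence. Of chance orderings of 2 against 2 values, 33.33% do not overlap. POU5F1, at 3616 and 3974 TPM, differs by a log2 change of 0.14 in TPM and of 0.00 after median-of-ratios scaling (0.0015).

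DNA replication genes rose in part. RRM2, a subunit of ribonucleotide reductase, rose from 57.5 ± 3.06 to 102 ± 4.33 TPM and TYMS (thymidylate synthase) from 117 ± 2.58 to 181 ± 0.847 TPM. In the DNA replication and S phase list, 19 of 34 members rose and 1 fell (25 and 1 when adjusted over the list alone). The one that fell, CDT1, was named after its value was seen and fell by 0.25 on the log2 scale. Under all 3 scalings 10 rose, and the list median was 0.15 relative to all genes. Without barasertib replicate 1, barasertib replicate 2 or DMSO replicate 1, 11, 11 and 12 rose and 0 fell, and 0 fell without the filter or the mean-variance trend. The S phase list had a camera adjusted p = 9.46e-05, and adjusted p = 0.389 with an estimated correlation. Among replication-dependent histone genes, H2BC21 rose from 8.86 ± 0.522 to 22.4 ± 1.17 TPM and H2BC12 from 21.8 ± 1.09 to 51.9 ± 10.3 TPM. Of 15 tested histone genes 12 rose and 1 fell (also 12 and 1 when adjusted over the list alone). Under all 3 scalings 11 rose, and the median was 0.88 relative to all genes. Summed over the histone list, expression was 786 ± 16.6 TPM with DMSO and 920 ± 0.93 TPM with barasertib, a smaller relative change than that median. Only 7 rose without barasertib replicate 1. The histone list had a camera adjusted p = 0.000675, and adjusted p = 0.369 with an estimated correlation. Of 25 DNA repair genes 11 rose and none fell (13 and 0 when adjusted over the list alone), 6 of them under all 3 scalings, with 1 falling under each of the other scalings. The repair genes that rose numbered 6 and 7 without barasertib replicate 1 or 2, and without the filter or the mean-variance trend 7. Among them, the checkpoint kinase gene CHEK2 rose from 42.5 ± 0.170 to 58.2 ± 0.447 TPM. Their median was 0.07 relative to all genes (camera adjusted p = 0.0128, and adjusted p = 0.389 with an estimated correlation). The repair call was lost after median-of-ratios scaling (camera adjusted p = 0.0655, in a range of 0.00319 to 0.0655 over the alternative settings at the preset correlation).

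Regulators of apoptosis and of cell cycle arrest changed in both directions. PMAIP1 (NOXA), which promotes apoptosis, rose from 65.4 ± 2.06 to 106 ± 10.4 TPM, and BID, of the same BCL2 family, from 3.31 ± 0.141 to 7.51 ± 0.886 TPM. Among 20 apoptosis regulators 5 rose and 3 fell (6 and 3 when adjusted over the list alone; camera adjusted p = 0.943), and 3 and 3 under all 3 scalings. The counts were 4 and 1 without barasertib replicate 1, 3 and 2 without barasertib replicate 2, 6 and 1 without DMSO replicate 2, and 4 and 1 without the filter. BAK1 was also among those that rose, and HRK, BCL2L1 and BCL2L2 fell (BAK1, BCL2L1 and BCL2L2 named after their values were seen). CDKN1A, an inhibitor of cyclin-dependent kinases, was at 2.55 ± 0.0361 TPM with DMSO and 2.08 ± 0.427 TPM with barasertib (limma adjusted p = 0.365). Of 13 cell cycle inhibitors and senescence genes 4 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.423). CDKN1C, CDKN2A, CDKN2C and LMNB1 (the last named after its value was seen) rose in TPM, but none of the 4 under all 3 scalings. CDKN2A (0.545 ± 0.132 TPM with DMSO, 1.81 ± 0.619 with barasertib) and CDKN2C (0.370 ± 0.171 and 1.65 ± 0.619) lay near the floor. Of the list, 0 members rose without the filter, 1 with FPKM, and 2 with a minimum of 5 TPM or without the mean-variance trend. HMGA2 fell, a call lost without any 1 of the 4 libraries (limma adjusted p of 0.0587 to 0.0840).

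Pluripotency genes changed in both directions. NANOG rose from 163 ± 6.26 to 252 ± 8.82 TPM, and GDF3, a ligand of the TGF-beta family, rose from 70.2 ± 3.07 to 168 ± 3.65 TPM. The DNA methyltransferase gene DNMT3B rose from 241 ± 17.9 to 446 ± 18.4 TPM. SOX2 fell from 451 ± 6.96 to 389.6 ± 11.8 TPM, a call lost without barasertib replicate 1 (limma adjusted p = 0.0644) or DMSO replicate 1 (limma adjusted p = 0.0608). Over its alternative settings, the limma adjusted p ran from 0.00302 to 0.0872, the highest without the mean-variance trend. POU5F1 (OCT4), at 3616 ± 130 TPM with DMSO and 3974 ± 35.4 TPM with barasertib, passed the test in TPM (log2 change 0.14, limma adjusted p = 0.0296). After quantile normalisation its log2 change was 0.32 (limma adjusted p = 0.0018, the lowest of its alternative settings), and after median-of-ratios scaling it was 0.00 (0.0015, limma adjusted p = 0.981, the highest). The POU5F1 call was also lost without barasertib replicate 1, barasertib replicate 2 or DMSO replicate 2 (limma adjusted p of 0.120, 0.0910 and 0.129), without the filter (0.129) and without the mean-variance trend (0.193). In the core and primed pluripotency list, 13 of 23 rose and 3 fell, also when adjusted over the list alone, and 9 rose and 3 fell under all 3 scalings. Without barasertib replicate 1, 8 rose and 3 fell, and without the mean-variance trend 9 rose and 1 fell. Among the members that fell with SOX2 was CRIPTO, named after its value was seen. The median was 0.17 relative to all genes (camera adjusted p = 0.0413, and adjusted p = 0.528 with an estimated correlation). The call was lost without barasertib replicate 1 (camera adjusted p = 0.0812), without barasertib replicate 2 (0.0643), with a minimum of 5 TPM (0.0775), with FPKM (0.0504) and without the mean-variance trend (0.0823), in a range of 0.00221 to 0.0823. Of 10 tested naive pluripotency genes 6 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.900), and 4 and 4 under all 3 scalings. Naive genes that rose numbered 3, 4, 5 and 4 without each library in turn, and those that fell 1, 2, 1 and 2. Without the mean-variance trend 5 rose and 2 fell, and without the filter 4 and 1 of 16. DPPA3 rose from 88.1 ± 4.74 to 207 ± 7.31 TPM and DNMT3L, a cofactor of DNA methylation, fell from 32.7 ± 3.39 to 17.6 ± 0.172 TPM. OOEP, KLF4 and KLF5, named after their values were seen, fell as well. Of 27 genes of chromatin silencing and DNA methylation 9 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.900), and 4 and 3 under all 3 scalings. After median-of-ratios scaling more fell than rose (4 rose and 6 fell), and after quantile normalisation 6 rose and 5 fell. Without each library in turn 5, 6, 6 and 7 of these genes rose and 1 fell, and without the mean-variance trend 6 and 1 did. The chromatin remodeller gene HELLS rose from 39.5 ± 0.219 to 70.2 ± 2.63 TPM, and DNMT3L, CBX5 and MPHOSPH8 fell, the last 2 named after their values were seen.

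Among lineage genes, 7 of 11 mesoderm genes rose and none fell (8 and 0 when adjusted over the list alone), 4 of them under all 3 scalings. Mesoderm genes that rose numbered 3 of 11 and 2 of 10 without barasertib replicate 1 or 2, and with a minimum of 5 TPM 3 of 5. KDR, a VEGF receptor, rose from 11.3 ± 0.206 to 19.7 ± 0.0142 TPM. The mesoderm median was 0.58 relative to all genes (camera adjusted p = 0.0228, and adjusted p = 0.389 with an estimated correlation), but 0.38 without DMSO replicate 2, 0.34 with a minimum of 5 TPM, 0.35 with FPKM, 0.30 without the filter and 0.23 with a pseudocount of 5. The call was lost without barasertib replicate 1 (camera adjusted p = 0.115), with a minimum of 5 TPM (0.384) and with FPKM (0.0545), in a range of 0.00301 to 0.384. Of 12 neural ectoderm genes 6 rose and 1 fell (8 and 1 when adjusted over the list alone; camera adjusted p = 0.160), and 2 and 1 under all 3 scalings. Without each library in turn 1, 2, 3 and 4 neural genes rose and 0, 0, 1 and 0 fell, and 0 fell without the filter or the mean-variance trend. NES (nestin) rose from 119 ± 2.94 to 285 ± 21.3 TPM, and STMN2, named after its value was seen, fell by 0.32 on the log2 scale. Of 5 endoderm and yolk sac genes FOXA3, HHEX and CXCR4 rose and LAMB1 fell, also when adjusted over the list alone (camera adjusted p = 0.243), and 2 rose and 1 fell under all 3 scalings. With any 1 of the 4 libraries left out 2 endoderm genes rose and 0 fell. The LAMB1 call was lost without any 1 of the 4 libraries (limma adjusted p of 0.0749 to 0.122). Of 8 trophoblast genes 4 rose and 1 fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.126), and also under all 3 scalings. With a minimum of 5 TPM, 2 of 4 rose. GATA2 rose from 0.747 ± 0.0823 to 4.12 ± 0.553 TPM, as did PGF, KRT8 and KRT18, the last named after its value was seen, while TFAP2A fell from 306 ± 0.0447 to 177 ± 12.1 TPM. After median-of-ratios scaling the neural list (camera adjusted p = 0.0380, range 0.0380 to 0.260) and the trophoblast list (0.0361, range 0.0361 to 0.763) passed. Of 5 cancer-testis antigens MAGEA2 and MAGEA6 rose, also when adjusted over the list alone (camera adjusted p = 0.378), 1 of them under all 3 scalings. Without barasertib replicate 1, barasertib replicate 2 or DMSO replicate 1, 0, 1 and 1 of them rose, and without the mean-variance trend 1. Lists with fewer than 5 tested members had no list test. Of 4 germ line genes DDX25 rose, of 3 zygotic genome activation genes CCNA1 and ZNF596 rose, and of 4 HOX genes HOXB2 and HOXD1 rose (1, 2 and 3 when adjusted over the list alone), with 1, 1 and 1 under all 3 scalings. No germ line gene rose without barasertib replicate 2 or DMSO replicate 2. Only 1 zygotic gene rose with any 1 of the 4 libraries left out, without the filter, with FPKM or with a pseudocount of 0.1, and 1 HOX gene without barasertib replicate 1, barasertib replicate 2 or DMSO replicate 2. Of the markers of blood, endothelial and fibroblast cells only THY1 and CD68 were tested, and THY1 rose (1 when adjusted over the list alone), also under all 3 scalings.

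Immediate early genes, transcribed within minutes of growth factor signalling, rose. EGR1 went from 3.36 ± 0.514 to 18.3 ± 2.01 TPM, and IER3 rose from 6.02 ± 0.00520 to 19.4 ± 1.02 TPM. DUSP6, a phosphatase of the ERK pathway, rose from 1.30 ± 0.255 to 5.91 ± 0.367 TPM. Of 16 tested members 15 rose, also when adjusted over the list alone, and 13 under all 3 scalings, at a median of 0.82 relative to all genes (0.52 with a pseudocount of 5). The immediate early list had a camera adjusted p = 1.28e-06, and adjusted p = 0.389 with an estimated correlation. In the Nodal and TGF-beta pathway list, 9 of 18 rose and 1 fell (11 and 2 when adjusted over the list alone). The 9 rose under all 3 scalings, with 2 falling under each of the other scalings and 0 without the mean-variance trend. The median was 0.29, and 0.45 and 0.18 with pseudocounts of 0.1 and 5 and 0.52 with a minimum of 5 TPM. The Nodal and TGF-beta list had a camera adjusted p = 0.00614, and adjusted p = 0.500 with an estimated correlation. ID3 rose from 109 ± 2.55 to 276 ± 25.7 TPM and BAMBI from 34.2 ± 3.79 to 85.4 ± 3.42 TPM. The member that fell was CRIPTO. WNT pathway genes went both ways (7 of 18 rose and 4 fell, also when adjusted over the list alone; camera adjusted p = 0.990), and 6 and 4 did so under all 3 scalings. Under each of the other scalings 6 rose and 6 fell, and with any 1 of the 4 libraries left out 6 rose and 2 fell. SFRP2, a secreted WNT antagonist, rose from 119 ± 12.1 to 393.5 ± 2.86 TPM and WNT5A fell from 7.97 ± 0.428 to 3.38 ± 0.0983 TPM. SP5, RNF43 and TCF7, named after their values were seen, fell as well.

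Matrix and cytoskeleton genes rose in part. Of 19 extracellular matrix genes 14 rose and 1 fell, also when adjusted over the list alone. Under all 3 scalings 7 rose, and the median was 0.26. Matrix genes that rose numbered 7, 11, 13 and 9 without each library in turn, with 0 falling, and without the mean-variance trend 10 rose and 0 fell. The matrix list had a camera adjusted p = 0.000811, and adjusted p = 0.389 with an estimated correlation. POSTN (periostin) rose from 5.40 ± 0.0275 to 16.3 ± 1.39 TPM, and the member that fell was LAMB1. Of 16 genes of actin and myosin contractility 10 rose, also when adjusted over the list alone, and 8 under all 3 scalings, with 1 falling under each of the other scalings, at a median of 0.20. The actin and myosin list had a camera adjusted p = 0.00247, and adjusted p = 0.401 with an estimated correlation. ACTB rose from 2656 ± 62.7 to 4457 ± 344 TPM. YAP and TEAD targets did not pass as a list (3 of 14 rose, also when adjusted over the list alone and under all 3 scalings, with 1 falling after quantile normalisation; camera adjusted p = 0.900), although AMOTL2 and CCN1 rose, the latter from 12.7 ± 0.193 to 35.0 ± 0.555 TPM, and CCN2 rose from 2.32 ± 0.376 to 8.13 ± 1.25 TPM. The epithelial and mesenchymal state list was split (7 of 19 rose and 5 fell, 7 and 7 when adjusted over the list alone; camera adjusted p = 0.182), and 5 rose and 4 fell under all 3 scalings. The counts were 5 and 7 after median-of-ratios scaling, 5 and 6 after quantile normalisation, and 4 and 4 without barasertib replicate 2. CDH1 (E-cadherin) fell from 20.3 ± 0.411 to 7.33 ± 0.372 TPM, and ESRP1, an epithelial splicing factor, fell from 16.6 ± 0.0510 to 4.62 ± 0.122 TPM. The integrin gene ITGB4 fell from 15.7 ± 1.51 to 4.98 ± 0.454 TPM, as did KRT19 and VIM, named after their values were seen, while KRT8, an epithelial keratin, rose from 360.4 ± 9.11 to 570.1 ± 27.1 TPM.

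Of 10 genes of NF-kB and secreted inflammatory factors 5 rose, also when adjusted over the list alone, 3 under all 3 scalings, at a median of 0.32. Only 2 rose without barasertib replicate 1 or 2, and with FPKM 3 of 7. The NF-kB median was 0.17 without DMSO replicate 2, without the filter or with a pseudocount of 5. The NF-kB list had a camera adjusted p = 0.0182, and adjusted p = 0.389 with an estimated correlation. TNFAIP3, an inhibitor of NF-kB, rose from 4.81 ± 0.0581 to 12.3 ± 0.538 TPM, and CXCL3, ICAM1 and NFKB2 were also among those that rose, the last named after its value was seen. The interferon response list did not pass (4 of 14 rose and 1 fell, 5 and 1 when adjusted over the list alone; camera adjusted p = 0.605), although ISG15 rose from 7.71 ± 1.45 to 26.6 ± 1.51 TPM and IFI6 from 6.11 ± 2.07 to 22.8 ± 1.94 TPM. Of the interferon genes 2 rose and 0 fell under all 3 scalings. Without each library in turn 2, 3, 2 and 2 rose and 0, 0, 0 and 1 fell, 2 fell after median-of-ratios scaling, and 0 fell without the filter or the mean-variance trend. RIGI and BST2 rose too, and IFITM1, named after its value was seen, fell by 0.16 on the log2 scale. In antigen presentation (6 of 10 rose and 1 fell, 7 and 1 when adjusted over the list alone; camera adjusted p = 0.111), B2M rose from 63.5 ± 1.44 to 137 ± 1.39 TPM and ERAP1, a peptidase of the ER, fell from 16.1 ± 0.335 to 6.63 ± 1.30 TPM. Of the antigen presentation genes 2 rose and 1 fell under all 3 scalings. Without barasertib replicate 1 or 2, 2 and 3 rose, and with a minimum of 5 TPM 3 of 7. The antigen presentation list passed after median-of-ratios scaling (camera adjusted p = 0.0361) and quantile normalisation (0.0469), in a range of 0.0361 to 0.420.

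Cytosolic ribosomal protein genes were lower by a small amount. RPL3 fell from 3752 ± 4.74 to 2847 ± 28.8 TPM and RPL10A from 2482 ± 5.01 to 1948 ± 10.7 TPM. Of 38 members 31 fell and none rose (33 and 0 when adjusted over the list alone). The median was -0.32 relative to all genes (camera adjusted p = 1.27e-23, and adjusted p = 0.191 with an estimated correlation), but -0.054 after quantile normalisation. Under median-of-ratios scaling all 38 fell, but under quantile normalisation 4 rose and 8 fell. Without the mean-variance trend 7 fell, and without the filter 20. The list was not called after quantile normalisation (camera adjusted p = 0.0522, in a range of 7.07e-24 to 0.0522). The elongation factor gene EEF2 fell from 5805 ± 89.3 to 4394 ± 5.37 TPM, and passed the test in that direction under each scaling.

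Metabolic genes rose in part. In the glycolysis and hypoxia list, 14 of 26 rose (18 when adjusted over the list alone), 8 of them under all 3 scalings. Glycolysis and hypoxia genes that rose numbered 8 without barasertib replicate 1 or 2, against 9 without the filter and 8 without the mean-variance trend. The median was 0.18, but 0.30 without DMSO replicate 1 and 0.072 without DMSO replicate 2. The glycolysis and hypoxia list had a camera adjusted p = 0.000317, and adjusted p = 0.561 with an estimated correlation. HK1, the first enzyme of glycolysis, rose from 78.9 ± 3.42 to 147 ± 3.12 TPM and PGK1 from 1127 ± 132 to 1694 ± 11 TPM. Of 27 mitochondrial respiratory chain genes 17 rose (18 when adjusted over the list alone), 6 of them under all 3 scalings. Respiratory chain genes that rose numbered 10, 11, 8 and 11 without each library in turn, and without the mean-variance trend 7, and 1 fell after median-of-ratios scaling. The median was 0.09, and 0.15 after quantile normalisation. The respiratory chain list had a camera adjusted p = 0.000464, and adjusted p = 0.401 with an estimated correlation. Of 24 cholesterol synthesis genes 5 rose and 5 fell in TPM (5 and 6 when adjusted over the list alone; camera adjusted p = 0.0578), and 1 and 5 under all 3 scalings. After median-of-ratios scaling 1 rose and 9 fell, and after quantile normalisation 1 and 8. Without each library in turn 1, 4, 2 and 4 cholesterol genes rose and 3, 3, 4 and 3 fell. The counts were 1 and 4 without the filter and 1 and 3 without the mean-variance trend. DHCR7, FDPS, LSS and FDFT1 were among those that rose, and STARD4, TM7SF2, SC5D, MSMO1 and SREBF2 fell (DHCR7, FDPS, LSS, FDFT1, MSMO1 and SREBF2 named after their values were seen). This list passed, downward, in 5 alternative settings, among them without barasertib replicate 1 (camera adjusted p = 0.0306) and without DMSO replicate 1 (0.0343), in a range of 0.0231 to 0.257. Of 25 lysosome genes 8 rose and 1 fell (11 and 1 when adjusted over the list alone; camera adjusted p = 0.106), the latter being NPC2, named after its value was seen. Under all 3 scalings 4 lysosome genes rose and 1 fell. None fell with any 1 of the 4 libraries left out or without the filter, and 5 rose and 0 fell without the mean-variance trend. The lysosome list passed without barasertib replicate 1 (camera adjusted p = 0.0408, range 0.0408 to 0.517). Medians and means above 0 stood beside a downward camera direction for apoptosis regulators, cell cycle inhibitors and WNT genes, none of which passed as a list. For the epithelial and mesenchymal list the median (0.005) and the mean (-0.12) differed in sign.

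**Figure D4:**
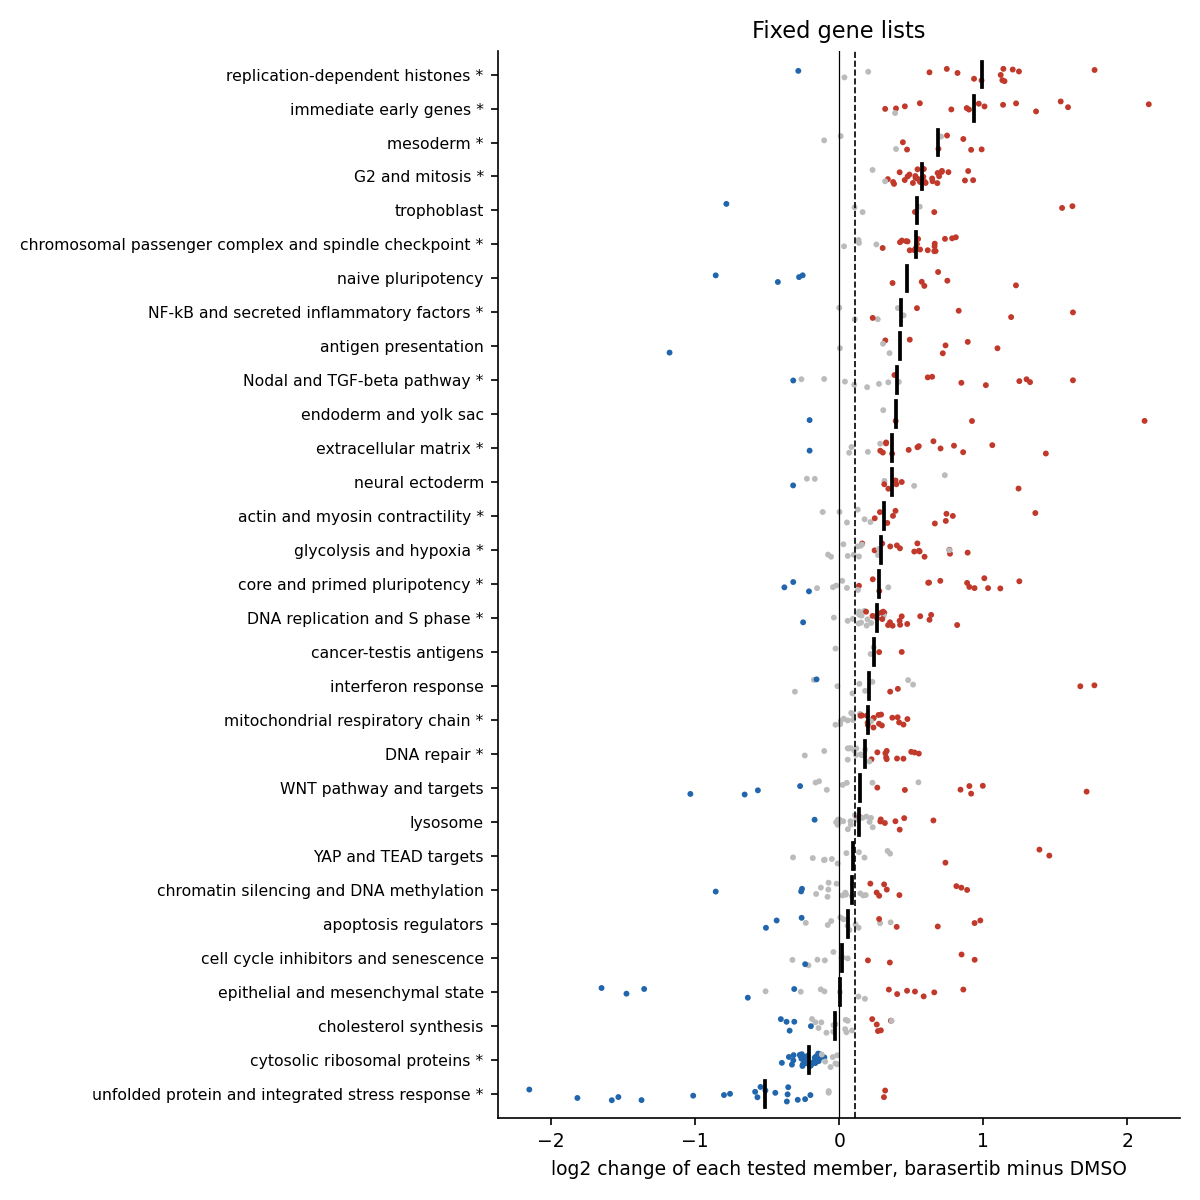
Each point is a tested member of a gene list described in the text, placed at its log2 change and coloured red (rose), blue (fell) or grey (did not pass), with a bar at the list median, a solid line at 0 and a dashed line at the median of all tested genes, 0.11. Asterisks mark the 16 lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 passed with an estimated correlation; the stress response list lies at a median of -0.51 and the histone list at 0.99, and 8 of the ribosomal protein genes fall under all 3 scalings, against 31 in TPM.

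No chromosome was called as a set. At the preset correlation, camera allows more variance the more genes a set holds, and chromosomes held 148 to 1436 tested genes. Small shifts would therefore not be called, and gains or losses that differ between cells were not measured. Over the 23 chromosomes tested (1 to 22 and X), medians of the log2 change lay between 0.09 on chromosome 19 and 0.14 on chromosome 11, and camera called none (0 at an unadjusted p under 0.05 as well, and 0 with an estimated correlation; lowest unadjusted camera p = 0.365 at the preset and 0.314 at an estimated correlation).

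Several large changes belong to loci whose reads can be assigned to a near-identical or overlapping gene and are uncertain. CEP170P1, SPIN2A, MIR3176 and the readthrough locus JMJD7-PLA2G4B are listed at 0 in both DMSO libraries. With barasertib, CEP170P1 was at 6.29 and 5.92 TPM, SPIN2A at 4.441 and 4.444, MIR3176 at 2.85 and 4.69, and JMJD7-PLA2G4B at 10.03 and 1.43. Sums with the parent, sister or host genes, which were not tested, did not all keep the direction of the locus. CEP170P1 plus CEP170 went from 26.6 ± 0.626 to 41.2 ± 0.304 TPM and SPIN2A plus SPIN2B from 11.95 ± 0.491 to 21.03 ± 1.6 TPM. JMJD7-PLA2G4B plus JMJD7 and PLA2G4B was lower with barasertib, at 40.6 ± 1.74 TPM with DMSO and 32.35 ± 1.38 TPM with barasertib. RPL13AP5, at 2962 ± 625 TPM with DMSO and 803 ± 336 TPM with barasertib, overlaps the ribosomal protein gene RPL13A, which was at 2278 ± 302 and 2752 ± 227 TPM, and their sum was at 5240 ± 324 and 3555 ± 108 TPM. MIR3652, at 2177 ± 16.0 and 545 ± 42.5 TPM, lies within HSP90B1 on the same strand. Of the called genes, 445 overlap another gene ID above 0 TPM on the same strand, among them SOX2, ATF5, RPL3, RPL10A and EEF2. The use of strand in counting is not given in the sources used here, so genes that overlap one on the other strand, such as THY1, TMEM200B, THBS2, KIF20A, TYMS and GATA2, could hold reads of both. The other named loci of this kind are FMC1-LUC7L2, FAM156A and ASMTL-AS1, which fell, and the histone gene H3C14. For FMC1-LUC7L2 plus FMC1 and LUC7L2 the sum was 76.4 ± 1.87 TPM with DMSO and 83.7 ± 9.36 TPM with barasertib, and for ASMTL-AS1 plus ASMTL 13.1 ± 0.0748 and 16.2 ± 1.18 TPM, so neither mean fell. FAM156A plus FAM156B was at 29.2 ± 4.13 and 26.4 ± 2.23 TPM, its libraries overlapping between groups as did those of the FMC1-LUC7L2 sum. MIR4787, which overlaps no other gene ID above 0 TPM, fell from 6.97 ± 2.09 to 1.43 ± 0.215 TPM. DOCK3, set beside it after its values were seen, was at 11.8 ± 0.617 TPM with DMSO and 8.26 ± 0.241 TPM with barasertib. Of the called genes, 68 are small RNAs. Libraries for polyadenylated RNA need not measure these, so their values may hold reads of other transcripts. H3C14 went from 2.64 ± 0.301 to 16.5 ± 1.76 TPM and from 3.95 ± 0.116 to 18.8 ± 2.56 TPM with its copies H3C15 and H3C13 added.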

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

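The removal of trends with level, GC content and length was the one setting chosen after the data were seen. The counts of called genes held within 1.5 times without a filter, with a stricter filter, with either pseudocount, with FPKM and with robust moderation; no chromosome was called under any setting. Scaling moved them to 1529 higher and 1891 lower with median-of-ratios scaling and 1649 and 1590 with quantile normalisation; 2566 and 2606 of the 4108 called genes remained called, 4 and 6 changed sign, and with quantile normalisation 2 more were at 0 (at 4 decimals). These scalings centre the genes near 0 by construction, which the deposited TPM do not. Without the mean-variance trend 674 genes were lower, and a 2-fold threshold left 292 higher and 87 lower, as a stricter rule must. Leaving out 1 library, with the lone sample assumed to vary like the other group, gave 1365 to 2181 higher and 601 to 699 lower genes; the lowest counts came without barasertib replicate 1 (1365 and 601) and without barasertib replicate 2 (1598 and 662), and without DMSO replicate 1 or 2 there were 698 and 699 lower, each from fewer libraries. Under the preset correlation 14 to 19 lists were called against 16 in the main test. With an estimated correlation 0 were called, and with fry 30, which does not compare a list with other genes. At 2 residual degrees of freedom, a list can miss the threshold even where its members are not correlated. The stress response list had an estimated correlation of -0.0322, and its unadjusted camera p went from 1.33e-19 to 0.00982. RPS2 and RPLP1, lower in TPM, lost that direction under quantile normalisation, RPS2 at a log2 change of 0 (at 4 decimals) and RPLP1 at 0.034, and neither passed the test there; the cause was not tested. Over all named genes and alternatives, 2058 values kept direction and side of the threshold, 222 lost the call and 2, RPS2 and RPLP1, lost the direction. For lists, 442 values held, 26 lost and 10 gained the call, and 58 gene or list values could not be had; 16 of the list values counted as held changed direction without a call in either setting. Same-numbered libraries did not deviate together (correlation of deviations 0.02). That value cannot tell whether they shared an experiment or culture, which the labels do not say. With the replicate block, 3218 genes were higher and 1080 lower, with 16 lists called. Depth is known only from the ratio of coverage to FPKM, so no counting interval is given.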

Other observations

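The tests of sequencing depth and of the medium were chosen after the results they measure had been seen, as was the removal of trends as a setting. The gene lists named in this part were written after the gene results, with HYOU1, CALR, DERL3 and CRELD2 already known to have fallen, so the ER folding list is not independent evidence. Genes given as examples here were named after their values were seen.

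The fall of ER genes extended beyond the stress response list. Of 22 genes for ER folding enzymes and ER-associated degradation, 0 of which the stress response list holds, 20 fell under all 3 scalings, while without DMSO replicate 1 19 fell and 1 rose. CALR (calreticulin) fell from 2783 ± 14.5 to 1148 ± 22.3 TPM, and PPIB from 1469 ± 28.2 to 676 ± 4.92 TPM (mean ± SD, n = 2). DERL1 and ERO1A did not pass. The list median was -1.02 relative to all tested genes (camera adjusted p = 1.21e-22, and adjusted p = 0.142 with an estimated correlation). Of 24 proteasome subunit genes 21 rose, 15 under all 3 scalings. Their median was 0.24 relative to all tested genes (camera adjusted p = 2.38e-08, and adjusted p = 0.196 with an estimated correlation), with PSMB3 rising from 461 ± 34.8 to 685 ± 7.0 TPM. Of 11 tubulin genes 9 rose, 8 under all 3 scalings (camera adjusted p = 2.07e-05, and adjusted p = 0.162 with an estimated correlation). TUBB2A rose from 762 ± 37.1 to 1482 ± 55.9 TPM and TUBB4A from 7.14 ± 0.494 to 17.1 ± 0.867 TPM. Among 18 cytosolic aminoacyl-tRNA synthetase genes 8 fell and 2 rose (camera adjusted p = 2.68e-05, and adjusted p = 0.273 with an estimated correlation); WARS1 fell from 493 ± 12.5 to 275 ± 0.521 TPM. AARS1 rose under all 3 scalings and VARS1 in TPM alone. After median-of-ratios scaling 12 of these fell, and 5 fell without barasertib replicate 1, barasertib replicate 2, DMSO replicate 2 or the mean-variance trend; in each of these settings, and without DMSO replicate 1, 1 rose. Of 11 cytosolic heat shock protein genes 6 rose and 1, HSPA8, fell (5 and 3 after median-of-ratios scaling), and the list did not pass (camera adjusted p = 0.160); HSPB1 rose from 123 ± 0.567 to 207 ± 17.3 TPM.

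Stress response genes were lower with barasertib. Scaling of the libraries does not account for this, since the highest list median over FPKM, median-of-ratios and quantile values was -0.53 (-0.5336). Nor do trends with expression level, GC content and transcript length, after whose removal the median was -0.549 (bootstrap interval -0.857 to -0.362, with values for all 23 members). This interval, like that for ribosomal protein genes below, resamples list members as if independent and holds no spread between libraries. It stays open whether the DMSO cultures, which may have held more cells after 4 days, stood in medium poorer in oxygen or glucose, which is known to induce HSPA5: hypoxia targets without glycolytic enzymes, 7 of 12 of them in a list fixed beforehand whose results had been seen, lay 0.098 above the median of all tested genes, but 0.190 above it without DMSO replicate 1 and 0.0186 without DMSO replicate 2 (2 of 12, BNIP3 and KDM3A, rose, and 0, 1, 5 and 1 of 12 without barasertib replicate 1, barasertib replicate 2, DMSO replicate 1 or DMSO replicate 2; camera adjusted p = 0.160), so they give no firm sign for or against oxygen-poor DMSO cultures. In the fixed glycolysis and hypoxia list 14 of 26 genes rose and 0 fell, opposite to what oxygen-poor DMSO cultures would give. That list had a camera adjusted p = 0.000317, and adjusted p = 0.561 with an estimated correlation. Its median, as given above, also moved with single DMSO libraries. The glucose-induced genes TXNIP (0.160 ± 0.0780 TPM with DMSO, 0.787 ± 0.338 with barasertib) and ARRDC4 (0.170 ± 0.0129 and 0.644 ± 0.170) were below the filter, and without it were higher by 0.61 (limma adjusted p = 0.0739) and 0.49 (limma adjusted p = 0.0485), the direction that glucose-poor DMSO cultures would give. With glucose genes near the floor and a hypoxia median that moves with single libraries, this cannot be told apart from an effect of barasertib on these genes, which remains a hypothesis.

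Ribosomal protein genes were lower in TPM. After removal of trends with expression level, GC content and transcript length, fitted on the other genes, their median was -0.072 (bootstrap interval -0.112 to -0.02), between the bounds set beforehand for and against that explanation, so part of the fall cannot be told apart from these trends. A hypothesis of shared control through the 5' TOP motif, the start sequence by which growth signalling regulates translation messages, asks that other 5' TOP genes fall too: these, none of them in a list fixed beforehand, lay at -0.354 relative to all tested genes, and at -0.133 after quantile normalisation, with 13 of 18 falling, 8 under all 3 scalings and 7 without the mean-variance trend (camera adjusted p = 9.95e-14, and adjusted p = 0.101 with an estimated correlation). No trend with level, GC content or length was removed from that list, so the same trends could produce both values. The 5' TOP list was also written after the gene results had been seen, so its fall is not independent evidence. TPM gives message abundance and not translation, so control of translation through this motif was not measured.

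More gene IDs were above 0 TPM with barasertib (18611 and 18562) than with DMSO (17532 and 17587); 480 were above 0 in both barasertib libraries and listed at 0 in both DMSO libraries, against 77 the other way. By total aligned bases, the gain was 5.63 times what the larger slope between replicates gives for a depth gap of 5.44%. That slope rests on the barasertib libraries alone, and the gap leaves out how reads were spread over genes. Median-of-ratios factors were 1.045 and 1.051 for barasertib and 0.953 and 0.956 for DMSO. A typical gene thus held a larger share of the library with barasertib, so depth per gene stays open as an explanation. Reads from genomic DNA remain a candidate explanation: of 391 olfactory receptor IDs, which these cells are not expected to use, 20 and 26 were above 0 with barasertib and 16 and 18 with DMSO, a ratio of 1.35 (1.353), in the direction that such reads would give. These counts are few, and weak transcription of silent genes would give the same ratio, so a biological source stays open and was not tested. The median level of the 480 was 0.139 TPM with barasertib, and 20 of them reached 1 TPM.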
